A study of Mus musculus with 254 samples.

How the data were processed

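Chromatin immunoprecipitation (ChIP) was hybridised against input DNA on 2-colour oligonucleotide arrays, with the immunoprecipitate in Cy5 and input in Cy3, per the labels. Pol II was measured on 37 genome-wide arrays per source; Pol II, H3Ac and H3K4me3 were measured on a condensed set of 4 arrays per source. Samples labelled "mes" were taken as the ES cells, because the series names 5 sources and the labels give the other 4 as organs; the data cannot check this reading. Groups were set from the labels before the data were examined.

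For the genome-wide and condensed arrays the authors deposited log2 ratios per probe, and the submitters' processing notes name limma, with no version. How these ratios were centred or scaled is not given in the sources used here; their array medians lay near 0. For the chromosome 11 arrays the scanner intensity of both channels was deposited, extracted with NimbleScan 2.2.26 on a design for mm5, per the file headers. The authors also deposited a normalized score per probe, which had an SD of 1 on every array and correlated with the scanner log2 ratio at 0.95 to 0.97; its scaling and centring are otherwise not stated. For expression the authors deposited GCOS signal intensity on a linear scale for 45101 probe sets, already at a 2% trimmed mean of 500 on every array.

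The plan fixed before the data were examined called regions from probe positions on all ChIP arrays, tested Pol II differences with limma over both array sets, and joined Pol II to expression. The genome-wide and condensed tables used here identify probes by place on the chip, and a comparison with the chromosome 11 design gave no match, so their genome positions were not used here and probes could not be matched between sets. The planned region calls, the limma test, the agreement between sets, the fixed gene lists, the cell type markers and the join to expression were therefore not run, and probes were compared within each array instead. Gene tables of GRCm38 were given, but do not hold the probe-set IDs and differ in build, so no coordinates or names were taken from them. All columns of the deposited tables were used.

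For chromosome 11, log2(Cy5/Cy3) of 383381 probes was centred on the array median, without loess or quantile steps, because many probes can carry signal. Window means over probes within 250 bp (at least 4 probes) were divided by an SD from the values below the median. The threshold was the lowest of a grid from 3 to 12 in steps of 0.25 at which regions called on sign-flipped values were at most 1% of those called, which gave 4.25 in brain, 4.75 in heart, 4.5 in kidney and 5 in liver. Passing probes were merged over gaps up to 500 bp, and regions of the organs by any overlap. Named regions are the 2 per organ with the largest excess in height over the next organ. Of the probes, 290964 had enough neighbours for a window. The number of arrays, 1 per organ, limits the precision.

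On the condensed set 2143 control spots per array were left out, leaving 388468 probes, and 815 genome-wide probes with a missing value were left out. Pearson correlations were taken within each array. Tail overlaps counted probes in the top and bottom 1% of each source. For marks at probes with a Pol II excess, the 2% of probes with the largest difference in rank between 1 source and the highest other were taken, and the marks were read as percentiles within their array. A per-probe form of the planned mirrored rule gave called shares from 0.000257% to 4.19% between arrays of the ES H3Ac profile and was not used further.

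Expression signals were scaled to a common 2% trimmed mean, which changed nothing because the deposited arrays already shared it. Probe sets were kept if their highest signal passed the pooled median of 175.9, and a pseudocount of 55.6, the 25th percentile of all signals, was added before log2, so folds of dim probe sets are understated. The rule for named genes asked for the top probe sets by excess; since these carry no gene name, their values and the named control genes are given instead, the latter chosen after the data were seen.

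The procedures were tested on simulated data. Regions of about 1 kb were planted on the real chromosome 11 positions (383381 probes). Only those with at least 4 probes within 250 bp of their centre were scored, so the shares do not cover sparsely tiled sites. At a log2 height of 2, 24.3% of 111 scored regions were found, at 3 94.5% of 109 and at 4 100% of 112. Of 301 calls, 1 lay outside planted regions. No region planted at 1 was found. An earlier simulation with a set noise level missed its own target at a height of 3. The noise was then taken from the real arrays, the height of 4 was added and the target was moved to it, so these shares are not a test fixed in advance. With marks coupled to Pol II of the same source the chosen probes differed by 31.1 percentiles, and by 0.63 without coupling (50000 probes). Simulated heart probe sets raised by log2 3 or 4 were all found among 45101. Only bright probe sets were raised, and well above the 4-fold limit, so the design made full recovery near certain. Dim probe sets and smaller changes were not simulated. Alternatives covered the deposited scores, normexp with loess, other windows, gaps, thresholds, scalings, pseudocounts, tails and correlation types. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.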

Results

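The series profiled chromatin and RNA from 5 mouse sources, namely embryonic stem (ES) cells, brain, heart, kidney and liver, to find where promoters are active in each. RNA polymerase II (Pol II), the enzyme that transcribes protein-coding genes, was mapped by chromatin immunoprecipitation on 37 genome-wide tiling arrays per source. It was mapped again on a smaller set of 4 arrays per source, together with acetylated histone H3 (H3Ac) and histone H3 trimethylated on lysine 4 (H3K4me3), modifications found at active promoters. H3K4me3 of the 4 organs was also hybridised to 1 array tiling a segment of chromosome 11, and RNA of each source to 1 expression array. The 254 samples thus held 185 genome-wide Pol II arrays, 60 arrays of the smaller set, 4 chromosome 11 arrays and 5 expression arrays. Each chromatin preparation was represented once per array set and each RNA once, so the data hold no replicate that could be used in a test, and differences between sources are given without p-values. Where a mean ± SD over arrays is given, the arrays carry different parts of the genome from the same preparation, and the SD describes the spread between those parts.

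The chromosome 11 arrays asked where H3K4me3 lies in each organ at a resolution of about 100 bp. Between positions 36912082 and 99375868 of chromosome 11 (mm5), H3K4me3 regions numbered 744 in brain, 783 in heart, 714 in kidney and 257 in liver. They covered 891 kb in brain, 674 kb in heart, 619 kb in kidney and 94.5 kb in liver. The median width was 1050 bp in brain, 750 bp in heart, 750 bp in kidney and 350 bp in liver. The median peak height, as the log2 ratio of immunoprecipitate to input over a window, was 3.81 in brain, 3.67 in heart, 3.43 in kidney and 3.34 in liver. Widths, coverage and heights depend on the threshold of each organ, which was lowest in brain and highest in liver. The lowest called height was 3.00 in liver against 2.34 in brain, 2.64 in heart and 2.49 in kidney, so these values do not rank the organs. At 117 merged regions called in every other organ, liver lay at least log2 1 below each of them. The same count was 6 for brain, 1 for heart and 0 for kidney. For these organs the count needs a call in liver, which called the fewest regions, so it does not rank the organs either. At most 4 regions per organ were called on the sign-flipped values.

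At these settings, most regions called in a given organ were also called in another. Of the merged regions with a call in the organ, 22.4% in brain, 21.4% in heart, 17.1% in kidney and 4.24% in liver were called there alone. The calls merged into 1083 regions, of which 212 (19.6%) were called in all 4 organs, 288 in 3, 127 in 2 and 456 (42.1%) in 1. Regions called in all 4 organs had a median width of 1650 bp and a median height of 4.51 in their highest organ, and those called in 1 organ 250 bp and 2.89. Merged width and highest height rise with the number of calling organs by construction. Of the brain regions 74.9% overlapped a heart region and 69.4% a kidney region, where 1000 circular shifts of the calls along the segment gave at most 6.72% and 6.05%. Liver regions were nearly a subset of the rest, since 89.8% of the merged regions with a liver call were called in all 4 organs and 10 in liver alone. Calling depends on the threshold, so a region not called in an organ is not shown to lack the mark there. The counts also depend on the settings. With the deposited scores 864 merged regions were called in 1 organ and 275 in 4. A mirrored share of 5% gave 1012 and 353, and windows of 500 bp on each side gave 372 and 295.

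**Figure D1:**
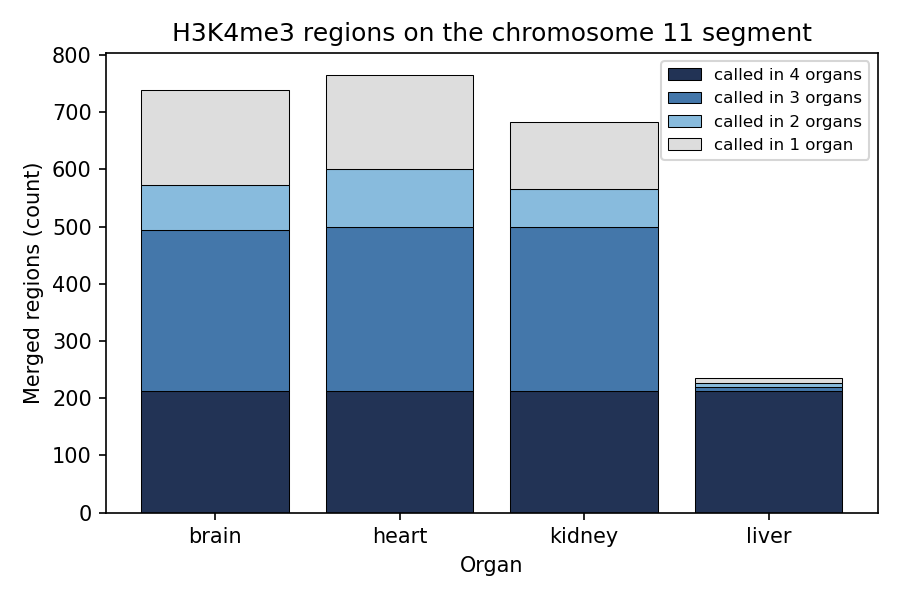
Merged H3K4me3 regions on the chromosome 11 segment (count, vertical axis) with a call in each organ (horizontal axis), divided by the number of organs that call the region. Each bar contains the 212 regions called in all 4 organs, which make up most of the liver bar.

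Regions called in brain alone numbered 165, of which 44 were at least 1000 bp wide at the lower threshold of brain, against 3 such wide regions for heart, 8 for kidney and 0 for liver. By height the order differed: an excess of at least log2 2 over every other organ was found at 91 regions in heart, 58 in kidney, 50 in brain and 9 in liver. The region with the largest brain excess lay at 54975073 to 54976568 on chromosome 11, with a height of 4.23 in brain, 0.43 in heart, 0.20 in kidney and 0.21 in liver. The next, at 41638707 to 41640539, reached 4.77 in brain and at most 1.13 in another organ. The widest merged region, 6134 bp from 92768023 to 92774156, was called in brain alone, at a height of 4.58, with 1.83 in heart, 1.81 in kidney and 0.57 in liver. The files used here do not pair these positions with genes, so no gene is named.

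Width counts only the probes whose window passed, and in heart, kidney and liver the regions with the largest excess were short. They were a 350 bp region at 49263734 to 49264083 and a 150 bp region at 99302849 to 99302998 in heart, with excesses of 4.53 and 4.07 over the next organ. In kidney they were a 150 bp region at 50703858 to 50704007 and a 50 bp region at 66781305 to 66781354, with excesses of 4.11 and 3.76. In liver they were a 150 bp region at 89128923 to 89129072 and a 50 bp region at 88416116 to 88416165, with excesses of 3.98 and 3.88. In each of these 6 regions the ratio in every other organ lay below the array median. With a window of 500 bp on each side, excesses fell to between 1.95 and 2.81.

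Among regions at least 1000 bp wide, a limit chosen after the values were seen, heart had its largest excess at 64881264 to 64882613, where it reached 4.34 and the next organ 1.28. Kidney had its largest excess at 95922098 to 95923923, at 3.77 against 0.82 in liver, 0.16 in heart and 0.10 in brain. Liver had its largest excess at 78111985 to 78113334, at 4.39 against 2.49 in brain, which also called the region. The region with the highest ratio in heart, kidney and liver was the same one, at 58839086 to 58841440, with 5.35, 4.80 and 4.45, and 5.13 in brain. Brain had its highest ratio, 5.32, at 95745952 to 95747430, a region called in all 4 organs.

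**Figure D2:**
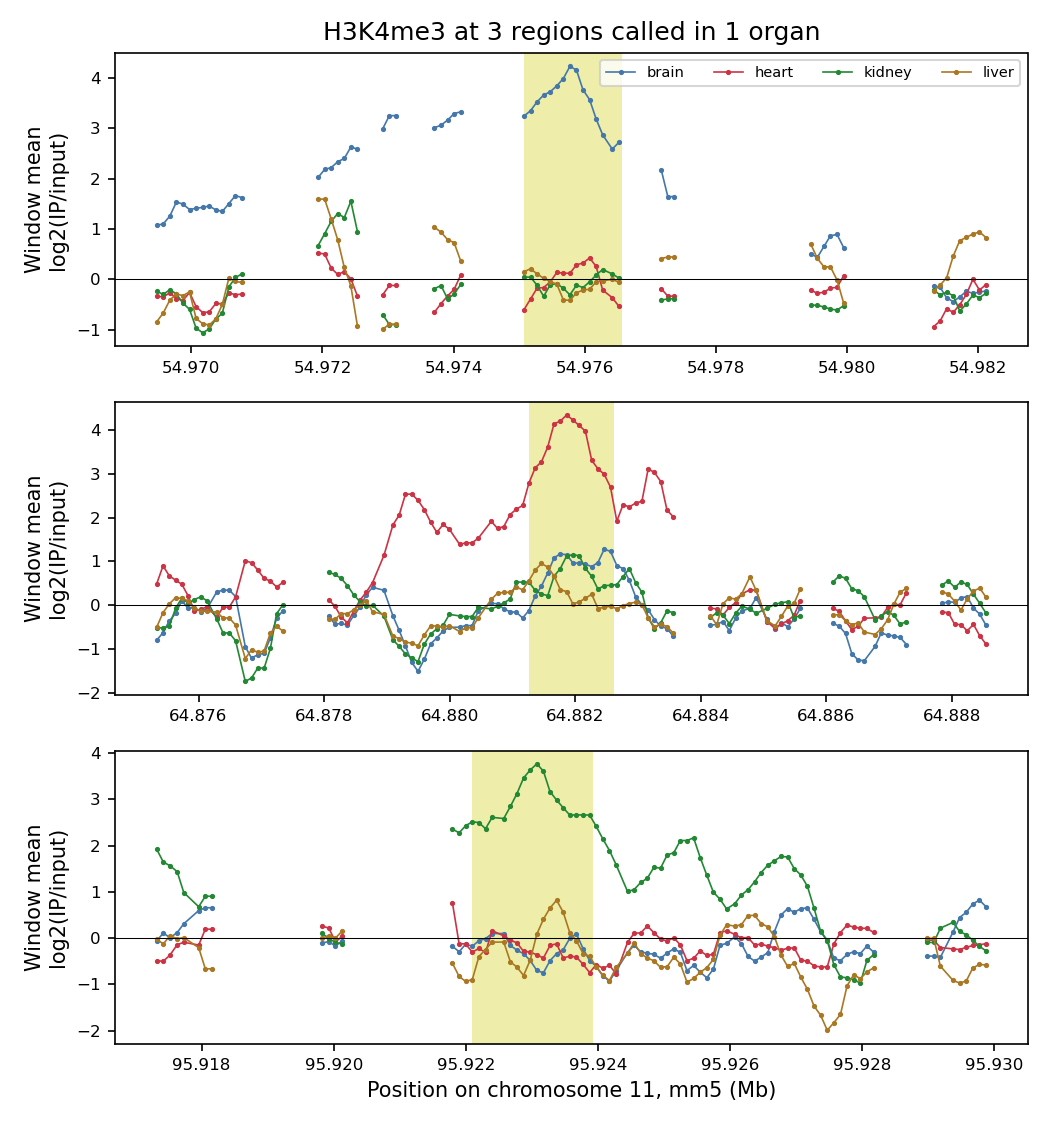
Window mean log2 ratio of immunoprecipitate to input (vertical axis) against position on chromosome 11 in Mb, mm5 (horizontal axis), around the regions of at least 1000 bp with the largest excess in brain, heart and kidney, from top to bottom. Points are probes, lines are organs, and shading marks the called region. The organ that calls the region reaches 4.23, 4.34 and 3.77.

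Regions were unevenly spread along the segment. A median of 14 merged regions fell in each 1 Mb bin, with 62 in the bin that starts at 69 Mb and 1 in the bin that starts at 37 Mb. Regions called in 1 organ alone also tended to neighbour each other: 51 neighbouring pairs of the merged regions were both brain-only, where 1000 shuffles gave a mean of 25.3 and at most 40. For kidney the count was 26, with a shuffled mean of 12.7 and at most 24, and for heart it was 34, within the shuffled range that reached 39. The longest brain-only run held 5 regions, from 97965941 to 98013730. Calls over 500 bp apart count as separate regions, and the shuffles moved labels over regions already cut. In brain, windows of 3.33 at 54974108 and 3.24 at 54975073 were cut in this way. With a gap of 1000 bp the regions called in 1 organ fell from 456 to 376. The shuffles therefore cannot tell clustered sites from 1 wide stretch counted as several regions.

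The genome-wide arrays asked which sequences carry Pol II in each source and which carry it in all. The probes of these arrays come with no genome position in the files used here, so they were compared probe by probe. Of 14184258 probes, 14569 lay in the top 1% of the log ratio in all 5 sources, while 113 lay in the bottom 1% in all 5. Top tails of 4 sources held 14943 probes and bottom tails 1669, and those of 3 held 20595 and 13057. Among probes in the tails of 2 sources the bottom tails held more, 77838 against 49014 in the top tails, and among those of 1 source 505346 against 416296. With tails of 5% the order for 1 source turned, to 1825386 bottom against 2237949 top probes. At that tail 3 sources also shared more bottom probes, 158700 against 81929 top probes, while all 5 shared 38958 top and 3822 bottom probes. On single arrays the number in all 5 top tails ran from 79 on array 37 to 689 on array 12.

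**Figure D3:**
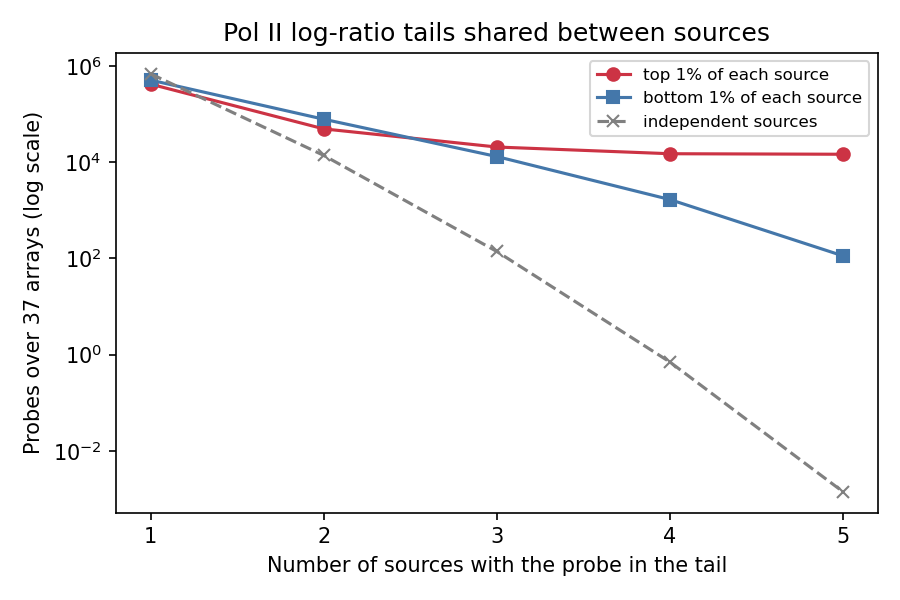
Number of Pol II probes over the 37 genome-wide arrays (vertical axis, log scale) against the number of sources that hold the probe in their tail (horizontal axis), for the top 1%, the bottom 1% and independent sources. At 5 sources the top tails share 14569 probes and the bottom tails 113.

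Kidney and liver shared the most high Pol II probes of any pair. Their top 1% tails had 34.8 ± 7.3 (SD, 37 arrays) times the overlap of independent lists, followed by brain and kidney with 32.7 ± 7.68. Heart and ES cells had the lowest value at this tail, 17.4 ± 5.58, but not at tails of 5% or 0.2%. In the bottom tails the same ratio was 7.34 ± 2.09 for kidney and liver and 11.3 ± 2.42 for heart and ES cells. With tails of 5%, heart and ES cells shared more in the bottom tails, at 4.38 ± 0.61, than in the top tails, at 2.93 ± 0.66. Across all probes the correlations were low: Pearson's r averaged 0.27 ± 0.050 between brain and kidney and 0.14 ± 0.035 between heart and liver. Heart and ES cells had an r of 0.23 ± 0.051, and by Spearman correlation were the highest pair, at 0.20 ± 0.048. Kidney had the most lopsided distribution, with positive skewness on 37 of 37 arrays, and heart the least, with positive skewness on 11. These probes are not independent replicates.

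By correlation across all probes, Pol II was the least similar target between sources on the smaller array set. The plan took regions of this set as chosen by the authors for Pol II binding on the genome-wide arrays. Pol II and the marks are thus compared over probes not chosen independently of Pol II. The top 1% tails gave no fixed order of Pol II and H3Ac. Brain and ES cells overlapped 19.2-fold for Pol II and 14.9-fold for H3Ac, and brain and heart 18.4-fold and 25.7-fold. Pearson's r across probes, averaged over the 10 pairs of sources, was 0.52 ± 0.026 (SD, 4 arrays) for H3K4me3, 0.47 ± 0.057 for H3Ac and 0.26 ± 0.040 for Pol II. By Spearman correlation H3Ac came first, at 0.39 ± 0.062, then H3K4me3 at 0.37 ± 0.037 and Pol II at 0.19 ± 0.037, so the order of the marks was not fixed. For H3K4me3 the most similar pair was brain and heart, at 0.64 ± 0.031, and the least similar was liver and ES cells, at 0.41 ± 0.039. For Pol II the most similar pair was kidney and liver, at 0.34 ± 0.095.

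The smaller set also asked whether Pol II goes with the marks of its own source. ES cells showed the largest such difference: their Pol II correlated with ES H3Ac at 0.47 ± 0.032 and with the H3Ac of the other 4 sources at 0.22 ± 0.030 on average. The difference between own and other sources was 0.25 ± 0.025 in ES cells, 0.10 ± 0.013 in brain, 0.10 ± 0.051 in liver and 0.086 ± 0.038 in kidney, positive on 4 of 4 arrays each. In heart it was -0.099 ± 0.049 and negative on all 4, since heart Pol II correlated with heart H3Ac at 0.088 ± 0.107. The top 1% tails differed: heart Pol II overlapped heart H3Ac 10.2-fold. With other H3Ac it was 6.53-fold for brain, 7.21-fold for ES cells, 8.01-fold for liver and 11.1-fold for kidney. In the bottom tails the overlap with heart H3Ac was the lowest, 6.40-fold against 6.65-fold to 9.59-fold. With H3K4me3 the difference in r between own and other sources was 0.11 ± 0.021 in kidney, 0.052 ± 0.024 in heart, 0.050 ± 0.044 in liver, 0.044 ± 0.031 in ES cells and 0.040 ± 0.046 in brain. The brain difference was smaller than its spread and positive on 3 of 4 arrays. By Spearman correlation the heart difference was also within its spread, 0.016 ± 0.038, and positive on 2 of 4 arrays. Brain Pol II also had the lowest correlation with H3K4me3 of its own source, 0.16 ± 0.070. At the top 1% tails its mean overlap was lowest with H3K4me3 of brain, at 5.30 ± 2.12-fold. The overlap was 6.44 ± 1.61-fold with liver, so these 2 differed by less than their spread. It was 7.74-fold with kidney, 8.42-fold with ES cells and 8.49-fold with heart H3K4me3. The order did not hold at the top 5% tails. There the overlap was 3.78-fold with liver, 4.096-fold with ES cells, 4.11-fold with brain, 4.23-fold with kidney and 4.46-fold with heart H3K4me3. All profiles are ratios to input DNA, so variation in input could raise r within a source, which was not tested.

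**Figure D4:**
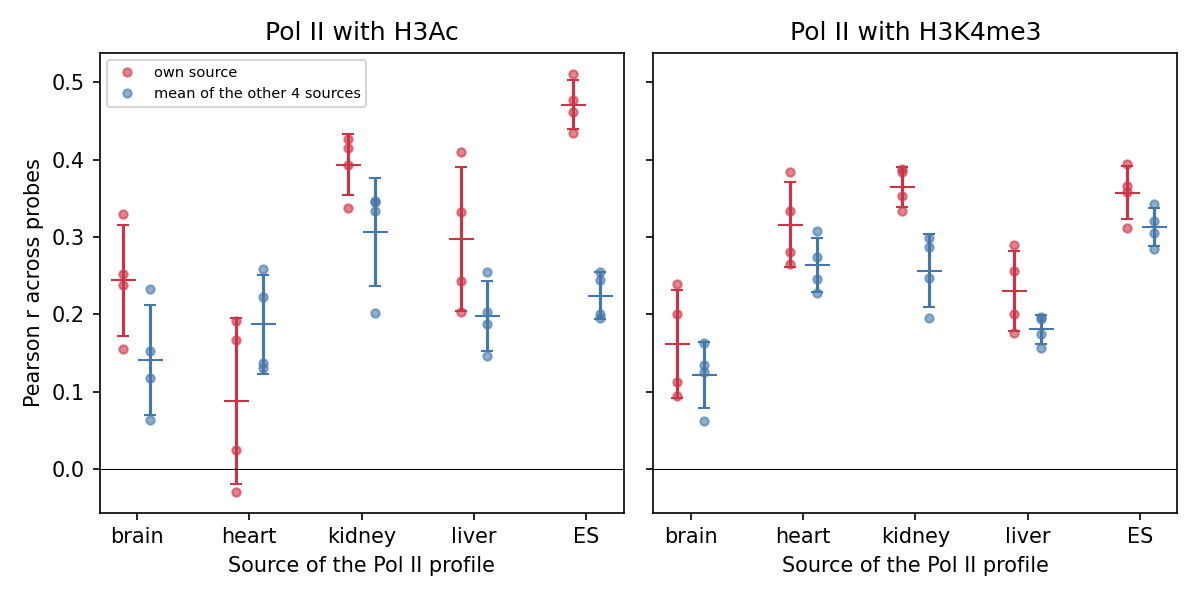
Pearson's r across probes (vertical axis) of each source's Pol II profile (horizontal axis) with H3Ac (left) and H3K4me3 (right) of its own source and of the other 4 sources on average. Points are the 4 arrays and bars the mean ± SD. Heart is the source whose own H3Ac lies below the others, by 0.099 on average.

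Probes were then chosen by Pol II alone, as the 2% of each array with the largest excess of 1 source over every other in rank. At the 31076 probes chosen for ES cells, H3Ac stood 18.9 ± 4.83 percentiles higher in ES cells than in the other sources on average. The H3Ac difference was 11.6 ± 1.97 percentiles at those chosen for liver, 4.61 ± 4.05 for kidney and 0.51 ± 0.47 for brain. H3K4me3 stood higher in the chosen source by 7.90 ± 1.27 percentiles in kidney, 6.02 ± 2.19 in liver, 5.29 ± 2.13 in ES cells and 2.45 ± 1.24 in brain. In the chosen source itself its mean percentile was 47.2 in kidney, 44.7 in liver, 50.0 in ES cells and 40.4 in brain. For H3Ac it was 51.4, 49.9, 62.8 and 41.2 in the same order. Except for H3Ac in ES cells, these probes thus lay near or below the middle of the array. In heart the differences were -2.46 ± 3.33 for H3Ac and 1.35 ± 1.80 for H3K4me3, both within their spread. When the excess was taken in SD units instead of ranks, which chose probes of higher Pol II, the heart differences were 4.07 ± 2.83 and 6.70 ± 2.56. That choice was made after the data were seen, and under it, at 2% of probes, both marks stood higher in the chosen source on 4 of 4 arrays for all 5 sources. At the top 5% in SD units heart H3Ac stood lower again, at -3.24 ± 1.20, and was positive on 0 of 4 arrays. The limit from input DNA given above holds here too.

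The expression arrays asked which transcripts set the sources apart. Of 34345 probe sets above the signal minimum, 1319 were at least 4-fold higher in brain than in every other source, 946 in ES cells, 554 in liver, 428 in heart and 403 in kidney. Fewer were at least 4-fold lower than in every other source: 297 in ES cells, 110 in liver, 45 in brain, 32 in heart and 7 in kidney. With a pseudocount of 1 the lower numbers became 1546, 583, 230, 472 and 568, and the higher ones 1159, 680, 1722, 627 and 479. ES cells and kidney then had more probe sets lower than higher, so which direction held more depended on dim probe sets. Kidney and liver shared the largest group, with 277 probe sets at least 4-fold higher in both than in the other 3 sources, ahead of 105 for brain and heart. Pearson's r across probe sets on the log2 scale was 0.73 between kidney and liver, 0.73 between heart and kidney and 0.53 between brain and liver. Each source has 1 array, so none of these differences has a replicate check.

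Genes with control probe sets on the array could be named. Pyruvate carboxylase, which makes oxaloacetate for gluconeogenesis, stood out in kidney and liver. Its 4 probe sets were 4.02-fold (log2 2.01 ± 0.38, SD over probe sets) above the mean of the other sources in kidney and 4.33-fold (log2 2.11 ± 0.81) in liver. The 3′ probe set read 2314 in kidney and 2877 in liver, against 435 in brain, 213 in ES cells and 100.3 in heart. Transferrin receptor, which takes up iron, was highest in ES cells, 2.55-fold (log2 1.35 ± 0.22, 3 probe sets) above the mean of the organs. It was also highest in ES cells under quantile normalization, at 2.58-fold, and when the arrays were scaled to the spike-ins, at 3.00-fold. Beta-actin, a cytoskeletal protein, was 0.554-fold (log2 -0.85 ± 0.10) in liver, the lowest source, and 0.478-fold and 0.544-fold under the same 2 scalings. Gapdh, a glycolytic enzyme, was 1.89-fold higher in heart, but 1.12-fold after quantile normalization, where brain was highest, and 1.05-fold after scaling to the spike-ins, where ES cells were highest.

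The spike-in controls, which are added in the same amount to each hybridisation, read 1.78-fold higher on the heart array than on the others, in 18 of 18 probe sets. Scaled to them, the number of probe sets higher in heart fell from 428 to 219, and the number lower rose from 32 to 138. The median probe set was 0.45 higher in brain than in ES cells on the log2 scale, a shift that quantile normalization removes. The files used here do not pair other probe sets with genes. Excesses over every other source reached log2 10.3 and 9.97 in heart and 9.81 in kidney, and probe sets lay below every other source by up to log2 8.95 and 8.60 in ES cells. The low signals behind these values were under the pseudocount of 55.6, which therefore sets their size. The heart values also come from the array on which the spike-ins read higher, although its trimmed mean equalled that of the others.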

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

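All tests in this part were chosen only after the result was seen. Across all probes, heart stood apart from the other sources in how Pol II went with H3Ac. At the top 1% tails the direction was not the same. There heart Pol II overlapped heart H3Ac 10.2-fold, more than H3Ac of brain, ES cells and liver, and less than that of kidney, at 11.1-fold. The difference in r between own and other sources was -0.099 in heart, negative on all 4 arrays, while its means in ES cells, brain, kidney and liver ran from 0.086 to 0.247 and were positive on all 4 arrays each. The difference between sources was not tested. An exchange of the heart H3Ac arrays with those of 1 other source is argued against: it raised the own-source r with both Pol II and H3K4me3 on 0 of 4 arrays for every source tried, although exchange with kidney raised r with Pol II alone by 0.127 in sum. Extreme heart H3Ac values are argued against as the cause, since ranks left a mean difference of -0.169 ± 0.056. The wide spread itself stays open, because Pearson's r does not change with scale and ranks keep any noise that widens it. Arrays with little signal of any kind are argued against by values alone. There r with heart H3K4me3 was 0.382 ± 0.025 and at least 0.351 on every array. By ranks it was 0.225 ± 0.044 and at least 0.164, short of the limit set for this test, so little signal stays open. These 2 tests replaced earlier ones, on 1 array and on Pol II of other sources, whose values were -0.056 and 0.337. The earlier ones ended as open. The first of them had been read as excluding the spread until an SD was added to its rule, after its value was seen. A loss of heart-specific signal stays open, since heart H3K4me3 went with heart H3Ac hardly better than with other H3Ac, by 0.031 ± 0.027 and by ranks -0.015 ± 0.053; a wrong label outside the series and heart biology stay open and untested.

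None of the 30 values over 4 arrays that were tested had an array standing apart from the rest, where chance gives about 1 in 20.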

How the results depend on the processing

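Alternatives with 500 bp minimum width, spike-in scaling, Spearman correlation, other tails, orders between results, other choices of probes, scalings of control genes, and each array left out were chosen after seeing the data. No paired analysis was possible because the Pol II probes of the 2 array sets share no identifier or position in the tables used here. For the same reason the alternatives listed beforehand for genome-wide regions, tissue differences, agreement between sets, histone marks at regions, Pol II overlap on chromosome 11 and gene lists were not run, nor was the median over probe sets of a gene. Leaving out 1 of 4 arrays cannot move a mean by more than its spread, so this was not read as a check. Normexp with loess gave no liver count, since no grid threshold met the rule there; brain, heart and kidney counts stayed within 1.5 times. Heart H3Ac at probes chosen by Pol II, -2.46 ± 3.33, changed sign under 2 other choices of probes given below. Among the results compared, directions turned for Pol II tails, the marks by Spearman correlation, expression counts with a pseudocount of 1 and some control genes, as given below. Apart from thresholds, which set how much is called, the cause of the changes below was not tested. On the liver array 2.30% of probes exceeded a log2 ratio of 2, against 3.14% to 3.82% in the other organs. A weaker array and fewer marked sites would both lower this share, so it cannot tell them apart. Absent liver calls are therefore not read as absence of the mark.

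On chromosome 11, the regions called in 1 organ numbered 864 with the deposited scores, 1012 with a mirrored share of 5% and 210 at a width of at least 500 bp. Regions called in 4 organs numbered 353 and 53 under the last 2 settings, and their share was 7.93% in the last. With the wider window 295 (30.2%) were called in 4 organs and 372 in 1. With the 5% share heart had 1219 and liver 447 regions; at 500 bp or more heart had 481, kidney 447 and liver 62. Named region excesses kept their sign under the deposited scores, normexp and the wider window.

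For expression, no scaling and no filter changed no count, as neither removed or moved a called probe set. Quantile normalization gave 82 probe sets lower in brain. A pseudocount of 1 gave lower counts of 230 in brain, 472 in heart, 568 in kidney, 583 in liver and 1546 in ES cells, so that higher minus lower counts turned to -89 in kidney and -387 in ES cells. A pseudocount 4 times larger gave 759 higher in brain, 281 in heart and 601 in ES cells, and 12, 2, 0, 23 and 59 lower in brain, heart, kidney, liver and ES cells. At 2-fold, the higher counts were 3150, 1603, 933, 1433 and 2835 in that order of sources and the lower counts 528, 555, 463, 846 and 1995. At 8-fold they were 572, 196, 212, 342 and 314 higher and 6, 3, 0, 18 and 56 lower. Scaling to the spike-ins gave 219 higher in heart, and 22, 138 and 2 lower in brain, heart and kidney. Against the other sources, quantile normalization turned Gapdh to log2 0.279 in brain and -0.182 in ES cells and beta-actin to 0.845 in brain, and scaling to the spike-ins turned beta-actin to 0.214 in brain and transferrin receptor to -0.430 in heart.

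With Spearman correlation, Pol II with H3Ac differed between own and other sources by 0.0875 in brain, -0.169 in heart and 0.198 in ES cells, Pol II with H3K4me3 by 0.0163 ± 0.0381 in heart (2 of 4 arrays positive), each moved by more than the spread. Within the spread, liver Pol II with H3Ac fell to 0.0653 ± 0.0488 and brain Pol II with H3K4me3 to 0.0243 ± 0.0352. By the same correlation H3K4me3 minus H3Ac in mean r between sources was -0.0242 instead of 0.0538, and on the genome-wide arrays Pol II correlated between sources at 0.145 on average instead of 0.203. Choosing probes in SD units gave H3Ac differences of 5.54 in brain, 4.07 in heart, 10.9 in kidney, 17.9 in liver and 25.3 in ES cells, and H3K4me3 differences of 6.70 in heart, 11.5 in kidney, 13.1 in liver and 10.3 in ES cells. In heart, H3Ac was 1.55 at the top 1% and -6.28 at the top 5%. Liver H3Ac was 9.49 at the top 5%, and kidney H3K4me3 was 9.22 at the top 1% and 6.10 at the top 5%. Probes in the top tail of all 5 sources exceeded those in the bottom tail 129-fold at 1%, 10.2-fold at 5% and 514-fold at 0.2%. The log2 of top over bottom for 1 source was -0.280 at 1% and 0.294 at 5%, for 2 sources -0.667 at 1% and 0.0647 at 0.2%, and for 3 sources 0.657 at 1% and -0.954 at 5%. For pairs it turned at 5% to -0.178 in brain and ES cells, -0.477 in brain and heart, -0.581 in heart and ES cells, -0.121 in heart and kidney and -0.233 in heart and liver. At 0.2% it was 1.69 in heart and ES cells and 3.44 in kidney and liver, the latter 0.576 at 5%.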

Other observations

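The test on liver was chosen only after the result was seen. The B1 repeat, a short interspersed element present in many transcripts, differed widely between sources. Its probe set read 66415 in heart and 50924 in brain, against 22254 in ES cells, 12713 in kidney and 4570 in liver. Liver remained lowest for B1 under quantile normalization and spike-in scaling, at 0.148-fold and 0.145-fold of the other sources, while brain instead of heart was highest under both. The ratio of 3′ to 5′ signal lay between 0.658 and 0.749 for Gapdh and between 1.61 and 1.86 for beta-actin.

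The last genome-wide array departed from the rest. On array 37 kidney and liver Pol II correlated at 0.45, the highest value for any pair on any array, and 79 probes lay in the top 1% of all 5 sources, the fewest of any array. ES Pol II had a skewness of 1.83 there, its highest value. That did not set the array apart, since ES cells reached 1.74 on array 36 and kidney 1.98 on array 15. The genome positions of this array were not used here.

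Regions called in 1 organ on chromosome 11 were short, with a median width of 150 bp in heart and in kidney, 200 bp in liver and 450 bp in brain. Dim input at most probes inside these regions was argued against: they had a median input percentile of 66.7 to 87.0 in the organ that called them. That lies above the middle of the array. Window means also took in probes up to 250 bp outside, which were not examined. A median cannot show a single dim spot either, so such spots stay open. A blemish on the chip behind most of these regions was also argued against. The median distance between probes of different regions lay within the range of 1000 random draws in all 4 organs, with 0 of 4 organs below every draw. A median cannot show a blemish behind a few regions, and probes outside the regions were again not examined, so that stays open. Width counts only the probes whose window passed the threshold, so a peak that barely passes gives a short region. Regions called in 1 organ had a median height of 2.89 in their highest organ. The lowest called heights were 2.34 to 3.00 by organ. How much of the shortness comes from this rule was not tested. Amplification of single fragments, and short marked sites, may also play a part and were not tested.

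Liver called fewer regions than the other organs. At the 281 regions called in brain, heart and kidney but not in liver, liver windows had a median percentile of 99.1 among all its windows, where random runs of the same lengths had 83.8, and 1 of the 281 lay below 1 SD. Their median was 4.20 SD, against the threshold of 5. This is consistent with weaker enrichment on the liver array; a lower amount of the mark in liver was not tested.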
